A study of Danio rerio with 12 samples.

How the data were processed

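RNA was sequenced in 12 libraries of adult zebrafish whole liver, 6 of wild type (glo2+/+) and 6 of fish homozygous for a CRISPR knockout allele of glyoxalase 2 (glo2-/-). The series title calls the gene glo2; its zebrafish symbol is hagh, printed as HAGH in the gene name table used here. All samples came from the Tg(fli1:EGFP) line, in which endothelial cells carry a green fluorescent protein, and the labels mark all of them as not trained. RNA was extracted with TRIzol and libraries were made by a BGISeq-500 procedure, per the labels' protocols. The labels give neither the sex of the fish nor a statement that each library came from a separate fish, so the p-values measure the spread between these samples, which may be partly technical.

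The authors deposited estimated counts per gene, which need not be whole numbers, for each library. They also deposited TPM, transcript abundances scaled to a sum of 1000000 per library, for the same genes. Reads were trimmed with Trim Galore 0.6.4 and quantified with kallisto 0.4.6 against build GRCz11, per the submitters' processing notes. How transcripts were summed to genes, and the annotation release, are not given in the sources used here. kallisto assigns reads that match several transcripts by likelihood, so values of near-identical gene copies are uncertain, and without a stated strand setting the same holds for overlapping genes. The tables list 32520 Ensembl gene identifiers, with no row lacking one. Of the estimated counts, 19.1% were not whole (by more than 0.001). Totals lay between 17433960 and 18465485 per library, and each TPM column summed to 1000000 or 999999.

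Gene names were looked up by identifier and 29201 of the 32520 identifiers had one. The name table gives many zebrafish genes a human-style symbol shared by several copies; such genes are printed with their identifier. Gene lists had been written with zebrafish symbols, so entries were matched by symbol in any case, then by a hand-made list of older and newer symbols, then by the symbol without its copy suffix. Of 1504 list entries, 98 matched no gene in the tables.

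Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr by genotype, TMM factors, glmQLFit and glmQLFTest, genotype as the only term). P-values were adjusted by the Benjamini-Hochberg method and the threshold was an adjusted p of 0.05. Standard errors and 95% intervals came from the quasi-likelihood F statistic. Per-library levels are CPM (counts scaled to a library total of 1000000) with TMM factors applied, and log2 CPM used a prior count of 2. Of 42 gene lists, 39 had at least 5 tested members and were tested with camera in limma 3.58.1, at a preset inter-gene correlation of 0.01, two-sided, against all tested genes. The same lists were tested with an estimated correlation and with fry, both by direction and for change in either direction (mixed). A list score is the mean log2 CPM of its tested members in a library; scores were compared by exact two-sided permutation tests over all 924 assignments.

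The design, the lists, the alternatives and the rule for named genes were set before the data were examined. The rule named the targeted gene and up to 10 genes per direction with the largest change past the threshold at an average log2 CPM of at least 1, of which at most 2 with clone-based names. Where no gene passed in a direction it took the 5 with the smallest p. It added up to 4 genes past the threshold per list, or the 2 with the smallest p in the glucose, insulin, glutathione and glyoxalase lists. It also added fixed genes (GLO1, haghl, LDHD, PCK1, g6pc1a.1, G6PC1 (ENSDARG00000013721), fbp1b, PKLR, GYS2, PYGL, both INSR and both IRS2 copies, IGFBP1, GCLC, GSR and vtg1). Of these haghl was not tested. A few genes that the rule named are not reported here.

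A list of genes close to hagh had been planned by position in GRCz11. It was replaced by neighbours in the RefSeq gene order of the assembly GRCz12tu, a later build of which no coordinate is given here. Genes were matched by symbol, synonym or symbol without a copy letter where this gave a single gene, which placed 75.3% of the 14509 tested genes. Neighbours were genes within 100 places of hagh; a width of 250 places was added after the results were seen.

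Alternatives were DESeq2 size factors, TMM factors without the vitellogenin genes, no filter and a stricter filter on low counts, DESeq2 1.42.0, limma-voom with sample weights, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), the replicate number as a block, the vitellogenin level as a covariate, 1 surrogate variable from sva 3.50.0, and leaving out each library. An exocrine pancreas covariate and a fit without the 3 libraries highest in pancreas markers were added after the data were seen. Chance was assessed by refitting 100 of the 462 possible splits of the libraries into 6 and 6, the genotypes among them. Libraries were compared for duplicates by chi-square; the smallest of 66 pairs had 33.6 per degree of freedom, so none was a repeat of another.

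The tests were checked on simulated counts for the 14509 genes with the real means, dispersions and depths, 6 libraries per genotype and 200 changed genes. The changed genes were drawn only from genes above a minimum mean CPM. The shares recovered thus do not cover the tested genes with the lowest counts. Over 5 simulations edgeR recovered 4.48% of genes changed 1.5-fold, 40.3% of those changed 2-fold and 89.1% of those changed 4-fold, and 3.65% of its calls were false. DESeq2 recovered 14.3%, 62.7% and 94.2%, with 16.2% of its calls false. A list raised 1.5-fold was found by camera in 5 of 5 simulations, in which genes varied independently.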

Results

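Glyoxalase 2 hydrolyses S-lactoylglutathione to D-lactate and glutathione and so completes the clearance of methylglyoxal, a reactive by-product of glycolysis. The series was set up to examine glucose metabolism in zebrafish with a knockout of its gene, and its RNA part compared adult whole liver in 6 glo2+/+ and 6 glo2-/- libraries. Each held between 17433960 and 18465485 estimated counts over 32520 genes, and 14509 genes had enough counts to be tested. The apolipoprotein gene apoa1b was the most abundant transcript in every library, with 9.12% to 15.9% of the counts. The median Spearman correlation was 0.934 within glo2+/+, 0.947 within glo2-/- and 0.941 between them.

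The targeted gene was examined first. HAGH (ENSDARG00000025338) mRNA was present at 94.8 ± 5.40 CPM in glo2+/+ and 81.5 ± 4.47 CPM in glo2-/- liver (SD, n = 6 each), so that 86.0% of the wild type level was left. The labels do not say what the allele removes, so the mRNA level does not show whether the enzyme was lost. All 6 glo2-/- libraries lay below all 6 glo2+/+ libraries, and an exact two-sided permutation test of log2 CPM gave p = 0.00216, the smallest that 924 assignments can give. The fitted log2 fold change was -0.22 (SE 0.09, 95% interval -0.42 to -0.02). It did not pass the threshold among all genes (edgeR adjusted p = 0.819). In the deposited TPM the levels were 61.0 ± 9.25 and 55.6 ± 8.22 (SD, n = 6 each) and overlapped (exact permutation p = 0.325).

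**Figure D1:**
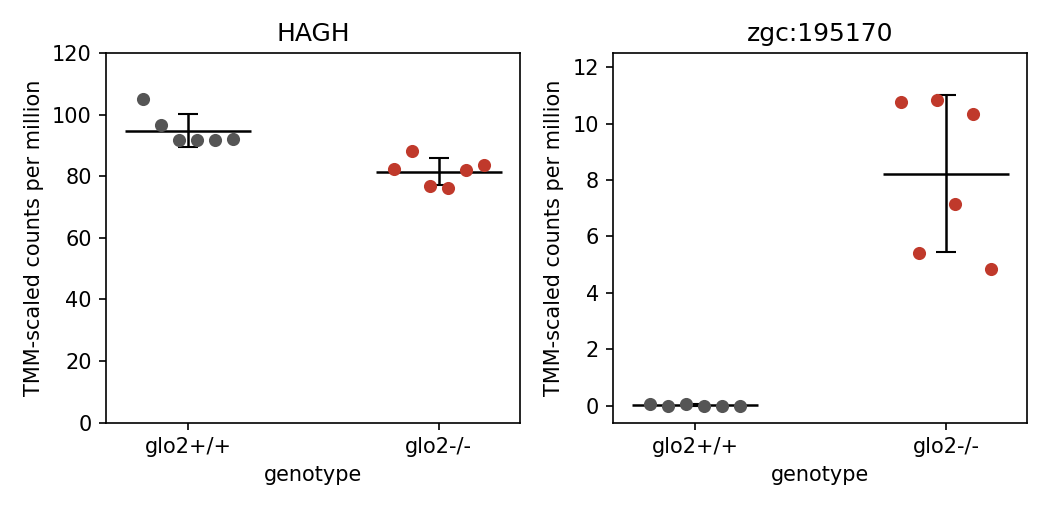
TMM-scaled CPM of HAGH and of zgc:195170 in each of the 12 libraries, by genotype; points are libraries, horizontal lines are means and error bars are SDs (n = 6). HAGH was lower in all glo2-/- libraries by a small amount, at 81.5 against 94.8 CPM, and zgc:195170 was nearly absent from glo2+/+ liver.

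A single gene passed the threshold between the genotypes. zgc:195170 (ENSDARG00000076264) rose in glo2-/- liver, with 100 to 211 counts in each of the 6 glo2-/- libraries. In glo2+/+ liver, 4 libraries had 0 counts and 2 had 1. Summed over libraries, 913 counts stood against 2, a ratio of 437 at equal depth (95% counting interval 121 to 3613, exact Poisson, which covers counting error only). The level was 8.23 ± 2.77 CPM against 0.0204 ± 0.0318 CPM (SD, n = 6 each). The fitted log2 fold change was 8.32 (SE 0.49, edgeR adjusted p = 2.14e-06), a value that depends on the prior count.

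No gene was lower in glo2-/- liver past the threshold by edgeR, with 495 genes lower and 358 higher at an unadjusted p under 0.05. The nominal expectation is about 725 in all. Other splits of the libraries gave from 298 to 1927 such genes, so the number is no excess beyond chance. The balance of lower and higher genes depended on the values used: limma on the deposited TPM gave 204 lower and 474 higher (pseudocount 1) or 194 and 472 (pseudocount 0.1). Without glo2-/- replicate 2, edgeR gave 491 in each direction. The 5 genes with the smallest p in that direction are given as values. The transcript of tmem86b, a membrane protein related to lysoplasmalogenase, stood at 4.15 ± 1.51 CPM in glo2-/- and 13.9 ± 5.34 CPM in glo2+/+ liver (SD, n = 6 each), with log2 fold change -1.74, SE 0.28 and edgeR adjusted p = 0.218. The others had an edgeR adjusted p of 0.340. Their log2 fold changes were -2.69 for si:ch211-39d8.1 (SE 0.49), -4.46 for si:ch211-276i6.1 (SE 0.85), -1.02 for si:dkey-183c2.5 (SE 0.20) and -0.94 for plxnb2a.3, a plexin gene (SE 0.19). All but si:ch211-276i6.1 were lower in all 6 glo2-/- libraries than in any glo2+/+ library. For si:ch211-276i6.1, glo2+/+ replicates 1 and 6 had 10 counts each, within the 4 to 14 of the glo2-/- libraries. The other glo2+/+ libraries had 121 to 531 counts, so its fold change was not shared by all wild type samples. DESeq2 called 10 genes higher and 24 lower, among them zgc:195170 and these 5, and 13 of its 34 calls fell on genes too low to enter the edgeR test.

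The chromosomal neighbourhood of hagh held several of the genes that separated the genotypes. Of 74 tested genes within 100 places of hagh, 10 had an unadjusted p under 0.05 (13.5%), against 5.75% of the 10847 other placed genes (one-sided Fisher exact p = 0.0101). The Fisher tests here take genes as independent. Of 100 splits of the libraries, 7 gave as many neighbours under this p, the genotypes among them. Adjusted over the 74 neighbours alone, 6 passed an adjusted p of 0.05 (edgeR). They were tmem86b, KAT2A (a histone acetyltransferase, log2 fold change -0.90, SE 0.20), DHX58 (an RNA helicase of antiviral sensing, -1.35, SE 0.33), aspdh (-0.57, SE 0.16), CDC27 (a subunit of the anaphase-promoting complex, 0.54, SE 0.11) and KRI1 (1.01, SE 0.20). They lay 55, 39, 38, 56, 78 and 14 places from hagh. Over all genes, DESeq2 called tmem86b (adjusted p = 1.82e-05), CDC27 (0.00338), KRI1 (0.00646) and KAT2A (0.0315). DHX58 and aspdh were not among its calls. Without overlap between the genotypes were tmem86b, KAT2A and CDC27, 3 of 74 or 4.05%, against 0.221% of the other placed genes (one-sided Fisher exact p = 0.000777). Further out, tmem150b, SLC25A17 (a peroxisomal carrier) and NUDT9 also did not overlap, at 146, 166 and 232 places. Apart from tmem86b these genes were named after their values were seen. The place of zgc:195170 was not used here, since its name had no match in that gene order.

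**Figure D2:**
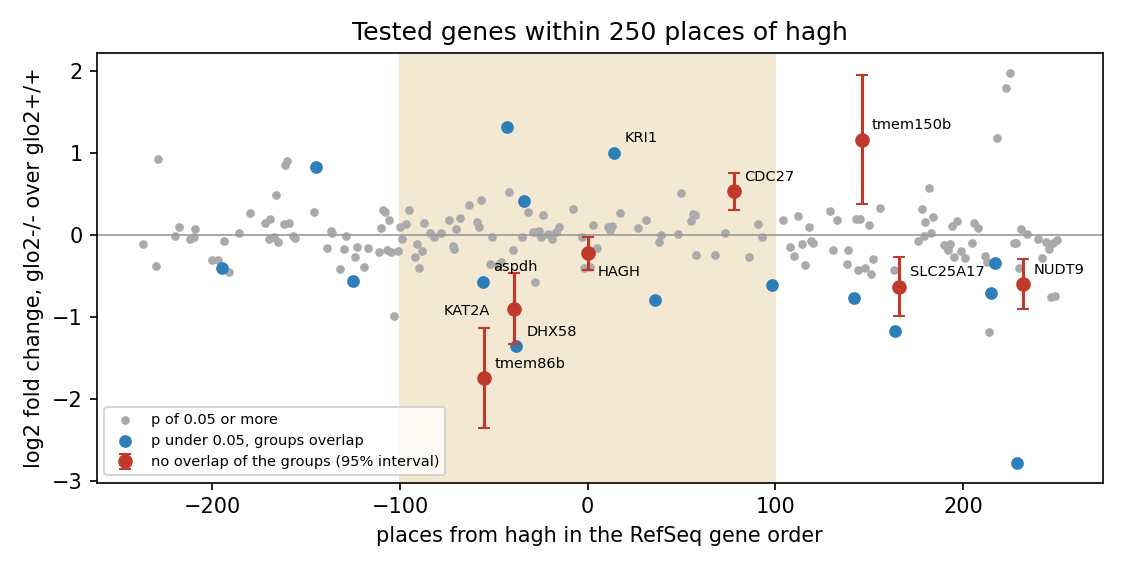
Log2 fold change (glo2-/- over glo2+/+) of the 192 placed tested genes within 250 places of hagh, hagh included, against their distance in places of the RefSeq gene order; the shaded band covers 100 places on each side. Red points with 95% intervals are the genes whose libraries did not overlap between the genotypes, and tmem86b, KAT2A and CDC27 lie inside the band.

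Genes of glucose metabolism were the question of the series, and none passed the threshold over all genes. Of 32 tested glycolysis genes, 17 had a positive and 15 a negative log2 fold change (camera adjusted p = 0.605), and 2 passed when adjusted over the list alone. These were HK1, a low-Km hexokinase, at 3.81 ± 0.933 CPM against 2.11 ± 0.634 CPM, and LDHA, the muscle-type lactate dehydrogenase, at 11.8 ± 3.43 CPM against 7.23 ± 1.49 CPM (glo2-/- first, SD, n = 6 each). LDHA was higher in all 6 glo2-/- libraries. Their log2 fold changes were 0.85 (SE 0.23) and 0.71 (SE 0.19), with an edgeR adjusted p of 0.668 over all genes. PKLR, the liver pyruvate kinase and far more abundant, stood at 1624 ± 556 CPM against 2429 ± 1021 CPM (log2 fold change -0.58, SE 0.30, edgeR adjusted p = 0.819).

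Gluconeogenesis genes had 9 positive and 17 negative log2 fold changes (camera adjusted p = 0.621). PCK1, which makes phosphoenolpyruvate from oxaloacetate, was at -0.05 (SE 0.65), with levels of 749 ± 602 CPM in glo2-/- and 777 ± 693 CPM in glo2+/+ liver (SD, n = 6 each). The glucose 6-phosphatase copies were at 0.13 for g6pc1a.1 (SE 0.24) and -0.50 for G6PC1 (ENSDARG00000013721, SE 0.78; -0.13 without glo2+/+ replicate 1 and -1.42 without glo2-/- replicate 4), and the fructose-bisphosphatase fbp1b at 0.12 (SE 0.14). Another G6PC1 copy (ENSDARG00000014967) had too few counts to be tested. The members with the smallest p were pyruvate carboxylase, PC (ENSDARG00000098766), at -0.37 (SE 0.18), and GOT2 at -0.30 (SE 0.14). Another PC copy (ENSDARG00000051939) was at 0.33 (SE 0.31). In glycogen metabolism 13 genes were positive and 13 negative (camera adjusted p = 0.784). Glycogen synthase GYS2 was at -0.08 (SE 0.15), the phosphorylase PYGL at -0.45 (SE 0.24) and PPP1R3D (ENSDARG00000077513) at 0.60 (SE 0.27).

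Insulin and IGF signalling genes were likewise divided, 20 positive and 32 negative (camera adjusted p = 0.605). The insulin receptor copies were at -0.22 (INSR, ENSDARG00000011948, SE 0.23) and 0.04 (INSR, ENSDARG00000071524, SE 0.25). The IRS2 copies were at -0.20 (ENSDARG00000037099, SE 0.66) and -0.02 (ENSDARG00000075282, SE 0.64), IGFBP1 at -0.63 (SE 0.50; -0.067 without glo2+/+ replicate 1), IGF1R (ENSDARG00000034434) at -0.68 (SE 0.35) and irs4a at -0.63 (SE 0.31). No member passed when adjusted over the list alone. The signs of PCK1, GYS2, g6pc1a.1, INSR (ENSDARG00000071524) and both IRS2 copies changed under at least 1 alternative setting.

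The partner enzyme of the pathway, GLO1, was at 34.2 ± 6.19 CPM in glo2-/- and 31.2 ± 4.12 CPM in glo2+/+ liver (SD, n = 6 each; log2 fold change 0.14, 95% interval -0.16 to 0.43). LDHD, which oxidises D-lactate, was at -0.22 (95% interval -0.61 to 0.16) and adh8b, an alcohol dehydrogenase, at -0.61 (SE 0.25). Of 23 glyoxalase and aldehyde clearance genes 10 were positive and 13 negative (camera adjusted p = 0.621). Glutathione genes numbered 13 positive and 25 negative (camera adjusted p = 0.476). GCLC, the rate-limiting enzyme of glutathione synthesis, was at 0.24 (SE 0.16), glutathione reductase (GSR) at -0.03 (SE 0.23) and gstt2 at -0.23 (SE 0.10). MGST2 was at -0.43 (SE 0.27), and between -0.72 and -0.35 with 1 library left out. The sign of GSR changed under several alternative settings. Nrf2 target genes had 16 positive and 15 negative members (camera adjusted p = 0.920).

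**Figure D3:**
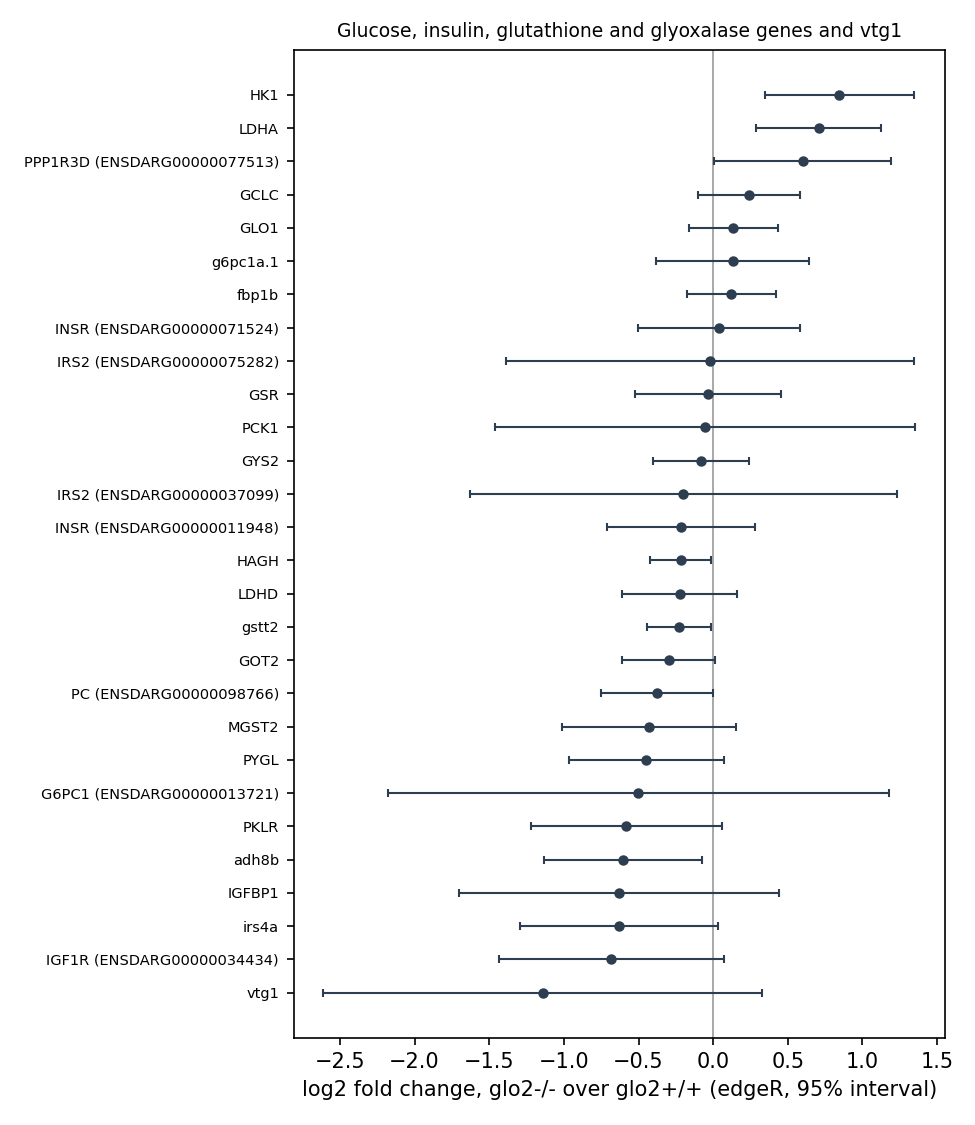
Log2 fold change (glo2-/- over glo2+/+) with 95% interval from edgeR for the named genes of glucose, insulin, glutathione and glyoxalase metabolism and for vtg1, n = 6 libraries per genotype. HK1 at 0.85 and LDHA at 0.71 have the highest values, and the interval of PCK1, from -1.46 to 1.35, spans both directions.

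Of 39 gene lists, 6 passed camera at the preset correlation. Interferon response genes were lower in glo2-/- liver: 29 of 35 had a negative log2 fold change, 10 of them with an unadjusted p under 0.05 (camera adjusted p = 3.3e-09). The adjusted p was 0.159 with an estimated correlation and 0.0933 with directional fry. Mixed fry, which does not test the direction, gave an adjusted p of 0.0268. No member passed over all genes by edgeR, while DESeq2 called isg15 (log2 fold change -1.83, adjusted p = 0.00338). Adjusted over the list alone, 2 passed by edgeR: isg15, a ubiquitin-like modifier induced by interferon, at 1.91 ± 0.974 CPM against 6.77 ± 3.22 CPM (glo2-/- first, SD, n = 6 each), and DHX58 at a log2 fold change of -1.35 (SE 0.33). Further members were stat2 at -0.84 (SE 0.28), CMPK2 at -1.04 (SE 0.34) and usp18 at -0.76 (SE 0.23). The mean log2 CPM of the list was 2.31 ± 0.156 in glo2-/- and 2.75 ± 0.199 in glo2+/+ (SD, n = 6 each), and 5 glo2-/- libraries lay below all glo2+/+ libraries (exact permutation p = 0.00433, adjusted over 39 lists 0.169).

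Macrophage markers moved with the interferon list: 19 of 20 were negative (camera adjusted p = 5.4e-06, adjusted p = 0.675 with an estimated correlation), among them c1qb at -0.69 (SE 0.24) and MFAP4 (ENSDARG00000090557) at -0.98 (SE 0.40). Fatty acid oxidation genes were also lower, 38 of 45 negative (camera adjusted p = 1.6e-05, adjusted p = 0.675 with an estimated correlation). The short-chain dehydrogenase ACADS was at -0.41 (SE 0.14), the trifunctional enzyme subunit HADHA at -0.42 (SE 0.15) and DECR1 at -0.53 (SE 0.20). List scores differed with an exact permutation p of 0.0173 for macrophage markers and 0.0390 for fatty acid oxidation, adjusted 0.338 and 0.506.

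Cholesterol synthesis genes were higher in glo2-/- liver: 26 of 28 had a positive log2 fold change with a median of 1.11, 9 of them at an unadjusted p under 0.05 (camera adjusted p = 7.4e-10, adjusted p = 0.690 with an estimated correlation). The farnesyl diphosphate synthase FDPS was at 429 ± 429 CPM against 115 ± 126 CPM, MSMO1 at 775 ± 526 CPM against 329 ± 159 CPM and SC5D at 99.1 ± 69.0 CPM against 38.9 ± 15.3 CPM (glo2-/- first, SD, n = 6 each). The spread within a genotype was as wide as the difference, with list scores of 6.19 ± 0.993 against 5.30 ± 0.877 (exact permutation p = 0.136). Cytosolic heat shock genes (23 of 31 positive, hsp70l at 2.53, SE 0.89) and unfolded protein response genes (34 of 45 positive, HSPA5 at 0.67, SE 0.38) each had a camera adjusted p of 0.000767, and an adjusted p = 0.747 with an estimated correlation. The heat shock call ended without glo2-/- replicate 3 (adjusted p = 0.0502) and the unfolded protein call without glo2+/+ replicate 3 (0.0808). The 6 camera calls were thus made only at the preset correlation, and without glo2+/+ replicate 4 there were 10. By mixed fry the interferon list alone passed (adjusted p = 0.0268).

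**Figure D4:**
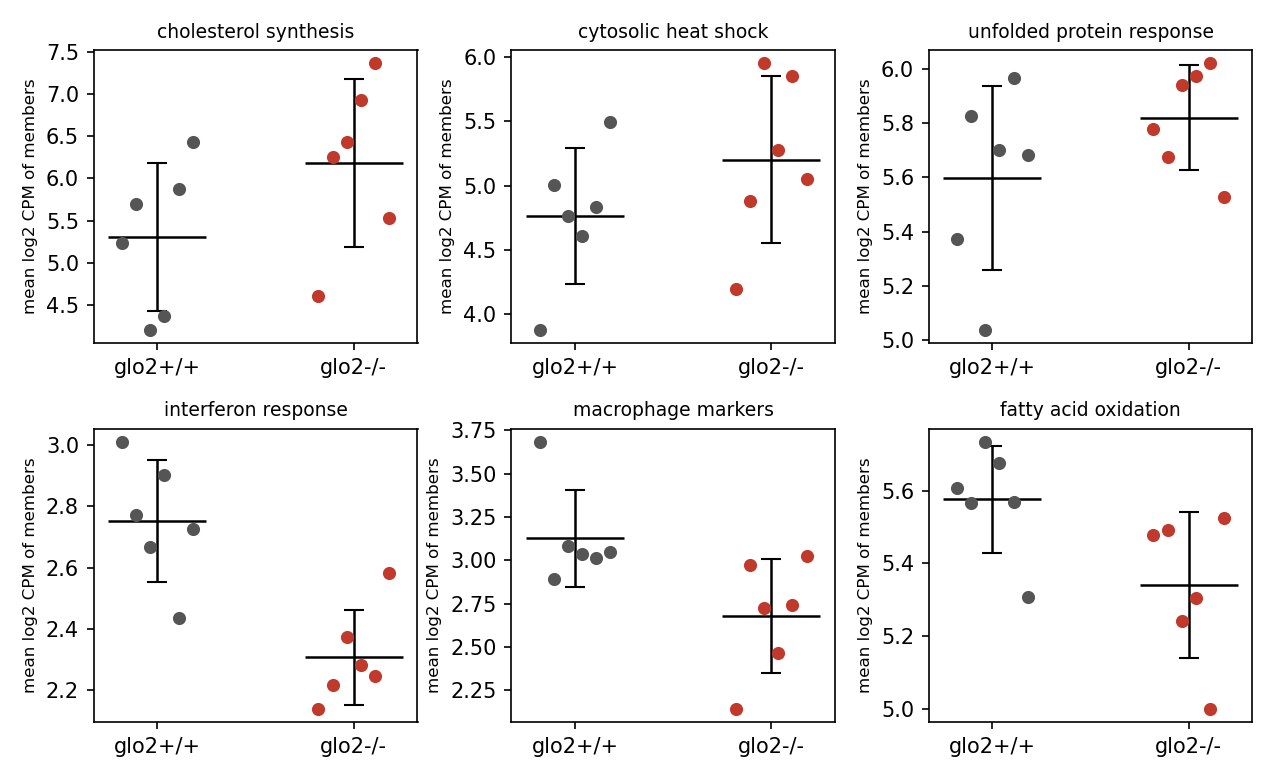
Mean log2 CPM of the members of the 6 gene lists that passed camera at the preset correlation, in each library by genotype; points are libraries, horizontal lines means and error bars SDs (n = 6). Interferon scores barely overlap (2.31 ± 0.156 in glo2-/-, 2.75 ± 0.199 in glo2+/+), whereas cholesterol synthesis scores overlap widely (6.19 ± 0.993 and 5.30 ± 0.877).

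Markers of other cell types and organs showed no further call with all libraries. The vitellogenin and oestrogen list, which marks female liver, had a camera adjusted p of 0.306, and vtg1 was at 0.957 ± 0.357 CPM in glo2-/- and 2.13 ± 3.02 CPM in glo2+/+ liver (SD, n = 6 each). The vitellogenin genes were low on average in every library, with a mean log2 CPM between -0.35 and 2.62. Their comparison between the genotypes thus rests on low counts. Exocrine pancreas markers varied most between libraries and had 26 of 27 members positive (camera adjusted p = 0.271), but their score differed by only 0.078 (3.51 ± 2.63 in glo2-/- and 3.43 ± 2.12 in glo2+/+, exact permutation p = 0.948). Camera adjusted p was 0.817 for neutrophil, 0.710 for lymphocyte, 0.626 for endothelial, 0.621 for bile duct and for erythrocyte, 0.764 for stellate cell and fibroblast, 0.168 for intestine, 0.139 for hepatocyte, 0.989 for adipocyte, 0.957 for kidney and interrenal and 0.823 for skeletal muscle markers. With 1 library left out it fell as low as 0.00125 for hepatocyte, 0.0143 for exocrine pancreas and 0.0478 for stellate cell and fibroblast markers.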

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

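The tests of density on other chromosomes, of chance for single gene lists, and of the camera calls under both pancreas corrections were chosen after the results were seen. Outlying libraries were sought in 154 sets of 6 values, and 7 were found where chance gives about 8. In glo2+/+ liver, tmem86b had a log2 CPM of 4.63 in replicate 4 (others 3.32 to 3.66) and MGST2 had 4.06 in replicate 6 (others 4.90 to 5.38). INSR (ENSDARG00000011948) had 3.62 in replicate 2 (others 4.72 to 5.01). The macrophage marker score was 3.68 in replicate 1 (others 2.89 to 3.08) and the pyruvate and TCA cycle score 5.68 in replicate 6 (others 5.87 to 5.91). In glo2-/- liver, LDHD had a log2 CPM of 2.15 in replicate 3 (others 2.70 to 2.88), and the insulin and IGF signalling score was 4.24 in replicate 4 (others 3.72 to 3.90).

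Genes close to hagh separated the genotypes more often than genes elsewhere. Chance could not be excluded for the 10 neighbours at p under 0.05, since 7 of 100 splits of the libraries gave as many (highest other 14). For the 3 neighbours without overlap, 1 of 100 splits, the genotypes themselves, gave as many (highest other 2). This makes chance less likely but does not exclude it, since only 100 of the 462 splits were drawn. Among placed genes on other chromosomes, 0 had as many such genes within 100 places, so a chromosome segment that came with the targeted allele is a candidate explanation. A regional effect of the edit itself was not tested. For zgc:195170 the segment cannot be told apart from other explanations: 13.5% of the neighbours had p under 0.05, but its own place was not used here.

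For the lower interferon list, 1 of 100 splits, the genotypes themselves, gave a camera p as small (1.69e-10, lowest other 1.7e-09). This makes chance unlikely for the list taken alone but does not exclude it, since only 100 of the 462 splits were drawn. Over 39 lists chance remains open (adjusted exact permutation p = 0.169). DHX58, the only member of the interferon list among the neighbours of hagh, does not carry the call. Without DHX58 the camera adjusted p was 4.2e-08 at the preset correlation. The full list passed camera only at that correlation (adjusted p = 0.159 with an estimated one). With fry the full list had an adjusted p of 0.0933 by direction and 0.0268 for change in either direction. With the macrophage score as a covariate, the score difference went from -0.44 (SE 0.10) to -0.29 (SE 0.11). Fewer macrophages may thus be part of it, and the data cannot decide, since 64.6% of the difference was left with an interval of -0.54 to -0.04. No gene is shared by these lists.

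For the higher cholesterol synthesis list, 15 of 100 splits gave a camera p as small (lowest other 7.5e-32), so chance remains open. With the exocrine pancreas score as a covariate, the score difference was 0.88 (SE 0.57), as without it (0.88, SE 0.54); the covariate had little to remove, since it differed by 0.078 between the genotypes (exact permutation p = 0.948). At the preset correlation, the list stayed past the threshold with this covariate (camera adjusted p = 1.71e-10) and without the 3 libraries highest in exocrine pancreas markers (1.43e-24). Without a correction it was at 0.690 with an estimated correlation, so it rests on the preset one. At the preset correlation 15 of 100 splits gave as small a p as the genotypes, so these calls cannot decide on pancreatic tissue. The values show only that the score difference did not depend on the exocrine pancreas score. With the heat shock score as a covariate the difference was 0.41 (SE 0.45). That SE is too wide to tell whether a stress response in some libraries could be the source.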

How the results depend on the processing

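zgc:195170 was called under every alternative, and HAGH stayed lower and short of the threshold. DESeq2 gave 10 genes higher and 24 lower, of which 21 of 34 were tested by edgeR. In simulated counts 16.2% of DESeq2 calls were false. The simulation held only genes tested by edgeR, so this share need not hold for the other calls. Leaving out each library gave 1 to 2 genes higher and 0 to 1 lower, HAGH at -0.23 to -0.19, and 5 to 10 lists past the threshold (10 without glo2+/+ replicate 4). The added genes were MPP3 (ENSDARG00000015184), higher without glo2+/+ replicate 6, and ABTB3 (ENSDARG00000063255), higher, and plxnb2a.2, lower, without glo2-/- replicate 6. Lists past the threshold numbered 10 without the 3 libraries highest in exocrine pancreas markers, a setting chosen after seeing the data. They numbered 0 with an estimated correlation and 0 with directional fry. The other settings gave lists within 1.5 times of 6. The replicate numbers did not pair the samples (correlations of same-numbered libraries -0.28 to 0.205), and the replicate block gave 1 gene higher, 0 lower and 6 lists.

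Exocrine pancreas markers turned to lower with 1 surrogate variable (camera adjusted p = 8.54e-13) and without the 3 pancreas-rich libraries (3.06e-07), both at the preset correlation. The latter follows largely from the selection, since 2 of the 3 libraries were glo2-/-. With an estimated correlation the list of all libraries was at 0.956. Several log2 fold changes changed sign, most of them near 0; vtg1 was at -1.14 with all libraries. With limma-voom GYS2 was at 0.0059 and IRS2 (ENSDARG00000075282) at 0.11. On TPM with pseudocount 1, GYS2 was at 0.024, GSR at 0.067 and PCK1 at 0.0089, and with pseudocount 0.1 at 0.024, 0.065 and 0.0092. With the vitellogenin covariate vtg1 was at 0.36, GYS2 at 0.0026 and INSR (ENSDARG00000071524) at -0.057. With 1 surrogate variable GSR was at 0.0022 and IRS2 (ENSDARG00000075282) at 0.10. Without the pancreas-rich libraries IRS2 (ENSDARG00000037099) was at 0.0060, GSR at 0.014 and IRS2 (ENSDARG00000075282) at 0.053. Leaving out each library, ranges were -0.13 to 0.093 for GSR, -0.14 to 0.016 for GYS2, -0.10 to 0.20 for INSR (ENSDARG00000071524), -1.02 to 0.34 for IRS2 (ENSDARG00000037099), -0.91 to 0.25 for IRS2 (ENSDARG00000075282), -0.42 to 0.54 for PCK1, -0.072 to 0.26 for g6pc1a.1 and -1.37 to 0.031 for vtg1. The cause was not tested. As many genes in the larger direction were found in 9 of 100 splits, the genotypes among them (1 against a highest other of 10). As many lists were found in 92 (6 against 14), so chance is excluded for neither count. The gene count does not weigh how far zgc:195170 differed, so it does not test that call. For the smaller direction the splits say nothing, since all 100 reach a count of 0 (highest other 4). A split that called 14 genes may point to a structure of the samples; this was not tested. At this depth and spread most 1.5-fold changes would be missed.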

Other observations

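The test of the relation between gene lists below was set before its result was seen. The genotypes did not overlap in 36 genes, 14 higher and 22 lower in glo2-/- liver, or 0.248% of tested genes where chance gives 0.216%. As many were found in 32 of 100 splits (highest other 143), so chance is not excluded for the number. Among them was NFE2L2, the transcription factor of the oxidative stress response, at 87.9 ± 15.5 CPM in glo2-/- and 121 ± 9.85 CPM in glo2+/+ liver (SD, n = 6 each; log2 fold change -0.46, SE 0.13), although its target list was divided. Others were APMAP at -0.71 (SE 0.15), the mitochondrial sulfurtransferase TST at -0.34 (SE 0.11), tigara, a fructose-bisphosphatase-like regulator of glycolysis, at -0.26 (SE 0.12), the leukotriene synthase LTC4S at -0.60 (SE 0.18) and degs1, a desaturase of ceramide synthesis, at 0.41 (SE 0.13). None of these passed the threshold over all genes by edgeR, DESeq2 called APMAP (adjusted p = 0.00638), and they were named after their values were seen.

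The remaining lists had no call with all libraries either. Camera adjusted p was 0.0916 for amino acid and urea metabolism (39 of 54 negative), 0.139 for xenobiotic metabolism and nuclear oxidative phosphorylation, 0.168 for the pyruvate and TCA cycle, circadian clock and ribosomal protein lists, 0.215 for inflammatory cytokines and immediate early genes, 0.306 for bile acids, 0.463 for the cell cycle, 0.681 for acute phase and complement, 0.784 for mitochondrially encoded genes and 0.957 for fatty acid and triglyceride synthesis. With 1 library left out it fell as low as 0.000103 for ribosomal proteins, 0.000184 for nuclear oxidative phosphorylation and 0.00595 for amino acid and urea metabolism. The lowest values were 0.0254 for immediate early genes, 0.0287 for inflammatory cytokines and 0.0324 for xenobiotic metabolism.

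Cholesterol synthesis and fatty acid oxidation scores ran opposite to each other from library to library. Deviations from the genotype means had Pearson r = -0.822 (permutation p = 0.00099, adjusted over 3 relations 0.00297) and Spearman rho = -0.839 (permutation p = 0.00115, adjusted 0.00345) over 12 libraries. Without the 2 libraries farthest from the median r was -0.838, and it was -0.900 within glo2+/+ and -0.779 within glo2-/- (n = 6 each). This is consistent with one axis of variation between samples, such as feeding state, that carries both lists; feeding state was not recorded in the labels and the hypothesis was tested on the data that raised it. Cholesterol and heat shock scores had r = 0.688 (permutation p = 0.0136, adjusted 0.0204) and rho = 0.741 (permutation p = 0.00774, adjusted 0.0116), and 0.608 without the 2 farthest libraries. Interferon and macrophage scores had r = 0.604 (permutation p = 0.0385, adjusted 0.0385) and rho = 0.448 (permutation p = 0.149, adjusted 0.149), and 0.591 without the 2 farthest libraries.

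Exocrine pancreas scores reached 7.14 in glo2-/- replicate 1, 6.09 in glo2-/- replicate 5 and 5.55 in glo2+/+ replicate 6. The mean log2 CPM of the vitellogenin genes was highest in glo2+/+ replicate 2, at 2.62.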
